A study of Mus musculus with 4 samples.

How the data were processed

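Total RNA was profiled in retinal aggregates grown from mouse embryonic stem cells and collected at day 4 or day 7 of differentiation. There were 4 arrays, 2 per day, and each array held 1 sample. Per the labels' protocols, RNA was extracted with Trizol and a column, copied into sense-strand cDNA, fragmented and labelled with biotin for an Affymetrix gene array. The day and the replicate number of each sample were taken from the sample titles.

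The authors deposited log2 expression values, 1 per probe set and array, made with RMA in Partek 6.5, per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a probe set on a log2 scale. Which of its settings were used is not given in the sources used here. The values were used as deposited, so a difference of 1 means a 2-fold difference in normalized signal. Background left in the signal makes folds of dim genes smaller than the true change. Quantile normalization also gives every array nearly the same distribution, so a change shared by most genes would not be seen.

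Of 41345 probe sets, 23521 named 1 gene in the platform annotation, 1814 named several and 16010 named none here. The gene identifiers of 23328 of those naming 1 gene were found in the RefSeq gene table of assembly GRCm38.p6, and this changed 0 symbols. That table was otherwise used for the order of genes along chromosomes. Probe sets naming several genes or none were left out of the tests by gene. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was kept, which gave 22180 genes. No value was missing (0 in the table).

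The day 7 minus day 4 difference of each gene was fitted with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, with the day as the only term and 2 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22180 genes, with a gene called at an adjusted p under 0.05. The variance prior had 5.07 degrees of freedom and an SD of 0.16. The SE of a difference is limma's moderated standard error, with a median of 0.156 over the genes. Adjusted p-values of single genes are limma's throughout. The number of arrays limits the precision.

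The 36 gene lists, the rule for named genes, the test and its main alternatives were fixed before the data were examined. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 36 lists, and again with the correlation estimated from the arrays and with fry, which tests whether the genes of a list move 1 way on balance. With an estimated correlation camera takes its p-value from the 2 residual degrees of freedom, so a list can fail there whatever its correlation. Members of a list were counted past the threshold over all genes, and also with p-values adjusted over the list alone. Named genes were the 12 with the largest rise and the 12 with the largest fall among called genes whose days did not overlap, leaving out predicted models, microRNAs and small nucleolar RNAs. In each list, up to 3 called members with the largest rise and up to 3 with the largest fall were added, or the member with the largest difference where none was called. A further set of R-spondin, Wnt, eye, neural and pluripotency genes was always named, and any other gene named to make up a count was chosen after its values were seen.

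The fit was tested on 20 simulated data sets with 200 changed genes among 22180. They took the gene means of these arrays and spreads drawn from the variance prior, with genes independent of each other. The fit recovered 0.373% of changes of 0.5 log2, 30.2% of changes of 1 and 96.8% of changes of 2, and 5.16% of its calls were false on average. Because limma called 2324 genes in the data, the limit for a call was less strict there than with 200 changed genes. These recovery rates therefore do not carry over to the data. With no change simulated the fit called 0 genes and camera 0 lists on average. Estimated correlations within lists reached 0.741 in the data (cholesterol synthesis). The simulation therefore does not show how often camera falsely calls a list of correlated genes. Alternatives were the replicate number as a block, leaving out each array, which leaves 1 sample for its day so that all spread comes from the other day, quantile normalization, centring each array on its median, filters at the 25th and 50th percentile of level, an intensity trend in the variance prior with and without robust estimation, and no variance prior. Others were the mean of a gene's probe sets, all probe sets of the table, and adjusted p limits of 0.01 and 0.1. Ranges of a gene's adjusted p over the alternatives leave out the fit without a variance prior, where 3 genes passed in all, and the set of all probe sets, which were run for the counts alone. Ranges of a list's adjusted p are those of the preset correlation. Permutation tests used SciPy 1.17.1 with NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with Matplotlib 3.10.9.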

Results

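Gene expression was measured on 4 arrays of retinal aggregates grown in matrigel from wild-type mouse embryonic stem cells, 2 from day 4 and 2 from day 7 of differentiation. The cells were a line derived from EB5, of 129/Ola origin, that carries GFP under the promoter of Rax (also called Rx), an eye field gene. The median log2 signal of an array lay between 5.68 and 5.77 and the interquartile range between 3.49 and 3.65. Across all 41345 probe sets, which are not independent replicates, the replicates correlated with r = 0.986 at day 4 and r = 0.991 at day 7, and arrays of different days with r between 0.972 and 0.978. More than 1 log2 separated the replicates for 161 named probe sets at day 4 and 79 at day 7, against 1193 to 1542 between days. The labels do not say whether the replicates were separate cultures, so p-values here measure only the spread between these samples, which may be technical.

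The title of the series names R-spondin 2 in the making of the optic vesicle and neuroretina, and its design sets day 7 against day 4. Of the secreted R-spondins, which strengthen Wnt signalling by keeping Wnt receptors at the cell surface, 3 of 4 rose by day 7. Rspo2 (probe set 17316793) rose 15.2-fold, from a log2 signal of 5.86 ± 0.42 at day 4 to 9.79 ± 0.02 at day 7 (SD, n = 2 per day, adjusted p = 0.000139). Rspo3 (probe set 17240012) rose 30.2-fold, from 5.35 ± 0.19 to 10.26 ± 0.02 (SD, n = 2, adjusted p = 3.73e-05). The rise of Rspo1 (probe set 17418403) was 4.31-fold, from 7.77 ± 0.16 to 9.88 ± 0.04 (SD, n = 2, adjusted p = 0.000373). Rspo4 stood at 5.78 ± 0.32 and 5.84 ± 0.08 (SD, n = 2, adjusted p = 0.917). Neural progenitor genes rose in 15 of 18 cases and forebrain genes in 7 of 18, while primed epiblast genes fell in 12 of 17. The shift of each of these 3 lists passed with camera but had an adjusted p = 0.366 with an estimated correlation.

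The largest rise among the genes named by rule was that of Wnt8b, a Wnt ligand of the dorsal forebrain, at 42.7-fold (log2 difference 5.42, SE 0.160, adjusted p = 3.38e-05). Next came Emx2, a homeobox gene of the developing cortex (35.8-fold), Rspo3, the transcriptional cofactor Dach1 (27.9-fold), the neural zinc finger gene Zic1 (25.3-fold) and the imprinted zinc finger gene Plagl1 (23.6-fold). Lix1, the non-coding RNA Rmst, the nuclear receptor gene Nr2f2, Scube1, the forebrain gene Fezf2 and the ephrin receptor gene Epha3 rose 16.2-fold to 22.1-fold. For Fezf2 the rise was 10.4-fold without day 4 replicate 1 and 28.2-fold without day 4 replicate 2. Among the same genes the largest fall was that of Fgf5, a growth factor of the epiblast, which was 26.1-fold lower at day 7 (log2 difference -4.71, SE 0.171, adjusted p = 3.96e-05). Rab25, a small GTPase of epithelia, was 17.4-fold lower, the kinase gene Pim2 14.7-fold, Vrtn 13.5-fold, and the calcitonin receptor gene Calcr and the fatty acid transporter gene Slc27a2 13.4-fold each. Falls of 9.02-fold to 12.1-fold followed for Hesx1, the de novo DNA methyltransferase gene Dnmt3b, Platr10, the testis histone gene H2bc1, Foxh1, a transcription factor of Nodal signalling, and Foxi3. Without day 4 replicate 1 or 2 the fall of H2bc1 was 6.05-fold or 15.4-fold in place of 9.66-fold, and that of Hesx1 27.5-fold or 5.31-fold in place of 12.1-fold. Hesx1 was the least even of these at day 4 (7.75 and 10.12), and limma gave it an adjusted p of 0.015. That p became 0.0748 without day 7 replicate 1, 0.0966 without day 7 replicate 2 and 0.121 with an intensity trend and a robust variance prior.

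**Figure D1:**
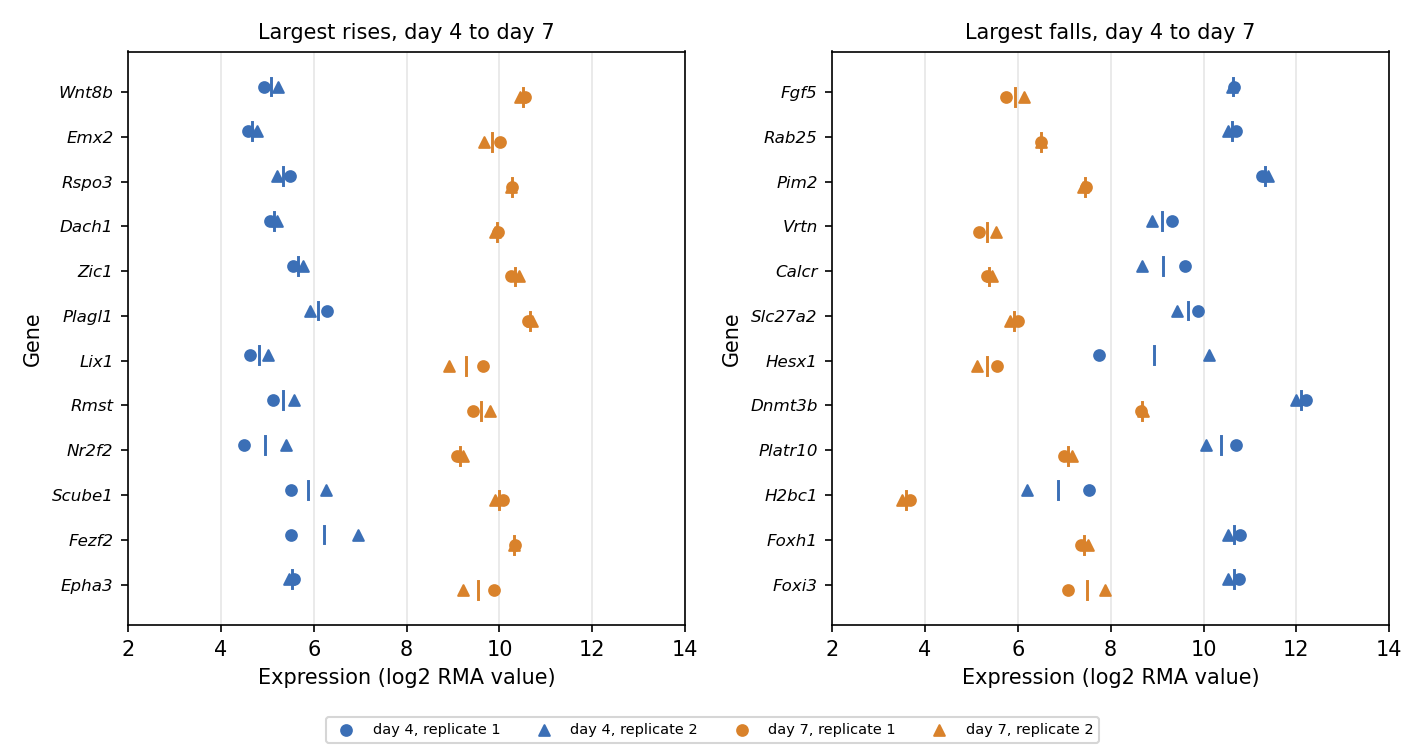
Log2 RMA signal (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis) on each of the 4 arrays, with day 4 in blue, day 7 in orange, replicate 1 as circles, replicate 2 as triangles and the mean of each day as a vertical line. For every gene plotted both day 7 points lie on the same side of both day 4 points, with Wnt8b moving from a mean of 5.08 to 10.50 and Fgf5 from 10.64 to 5.93.

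limma called 2324 of 22180 genes, 1364 higher and 960 lower at day 7, and 1160 of them differed at least 2-fold (695 higher, 465 lower). Both day 7 values lay outside the day 4 values for 11259 genes (50.8%, with 33.3% given by chance). The call count was 887 without day 7 replicate 1 and 994 without day 7 replicate 2. Without a variance prior 3 genes passed, with 3557 at an unadjusted p under 0.05. Of the 36 gene lists camera called 26, 19 towards higher and 7 towards lower expression. None (0) passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 17 passed with camera on genes above the median level. With fry 3 passed, at an adjusted p of 0.0495 each: primed epiblast, neuroectoderm and neural crest. For called genes with a day mean under 4.60, the 25th percentile of all genes (H2bc1, Mab21l1, Trpm1, Neurod4, Nhlh1, Dcx, Adm and Postn here), the fold is a lower bound with respect to background alone, not to the spread between arrays. Some genes named below to complete short counts or as examples lay outside the naming rule and were chosen after their values were seen. They were Trpm1, Pmel, Olig2, Cdon, Gli1, Pfkp, Ldha, Cited1, Dkk1, Frzb, Sfrp1, Sfrp2, Wif1, Shh, Ptch1 and Hhip.

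In the list of R-spondins and regulators of Wnt receptors, 10 of 21 measured genes rose, 1 fell and 10 were not called (13 and 2 adjusted over the list alone). The list was shifted upwards (camera adjusted p = 4.78e-07, adjusted p = 0.377 with an estimated correlation). Besides Rspo1, Rspo2 and Rspo3, the R-spondin receptor gene Lgr5 rose 3.92-fold, from 5.25 ± 0.02 to 7.22 ± 0.55 (SD, n = 2, adjusted p = 0.00326). The related receptor gene Lgr4 stood at 9.83 ± 0.08 and 9.39 ± 0.32 (SD, n = 2, adjusted p = 0.21). Lgr6 stood at 5.99 and 6.09 (adjusted p = 0.77). Several genes of secreted Wnt inhibitors rose: Dkk1 3.26-fold (adjusted p = 0.000737), Frzb 2.99-fold (adjusted p = 0.00186) and Sfrp2 1.73-fold (adjusted p = 0.026). The inhibitor genes Sfrp1 and Wif1 were not called. The ubiquitin ligase genes that R-spondins counteract were not called, Znrf3 with a log2 difference of 0.50 (adjusted p = 0.0717, and 0.0489 with each array centred on its median, 0.0356 to 0.365 over the alternatives) and Rnf43 with 0.01 (adjusted p = 0.993). The fall was that of the secreted Wnt inhibitor gene Sfrp5 (log2 difference -0.95, adjusted p = 0.0178, and 0.141 without day 7 replicate 1, 0.00685 to 0.141 over the alternatives).

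Among 26 Wnt ligand and Frizzled receptor genes 11 rose, 1 fell and 14 were not called (15 and 2 adjusted over the list alone, camera adjusted p = 5e-07). The shift had an adjusted p = 0.366 with an estimated correlation. Wnt8b led, followed by Wnt7b at 10.1-fold (log2 difference 3.34, SE 0.222) and Fzd3 at 3.45-fold. The Frizzled gene Fzd7 fell by 0.71 log2 (adjusted p = 0.0218, and 0.0501 without day 4 replicate 2, 0.181 without day 7 replicate 1 and 0.102 without day 7 replicate 2). Target genes of the Wnt/beta-catenin pathway rose in 6 of 15 cases, with 9 not called and 0 lower (8 higher and 1 lower adjusted over the list alone). The feedback inhibitor gene Axin2 rose 4.36-fold, from 6.47 ± 0.18 to 8.59 ± 0.00 (SD, n = 2, adjusted p = 0.000384), and Nkd1, another feedback inhibitor gene, 4.76-fold. This list was shifted upwards too (camera adjusted p = 2.05e-05, adjusted p = 0.366 with an estimated correlation).

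**Figure D2:**
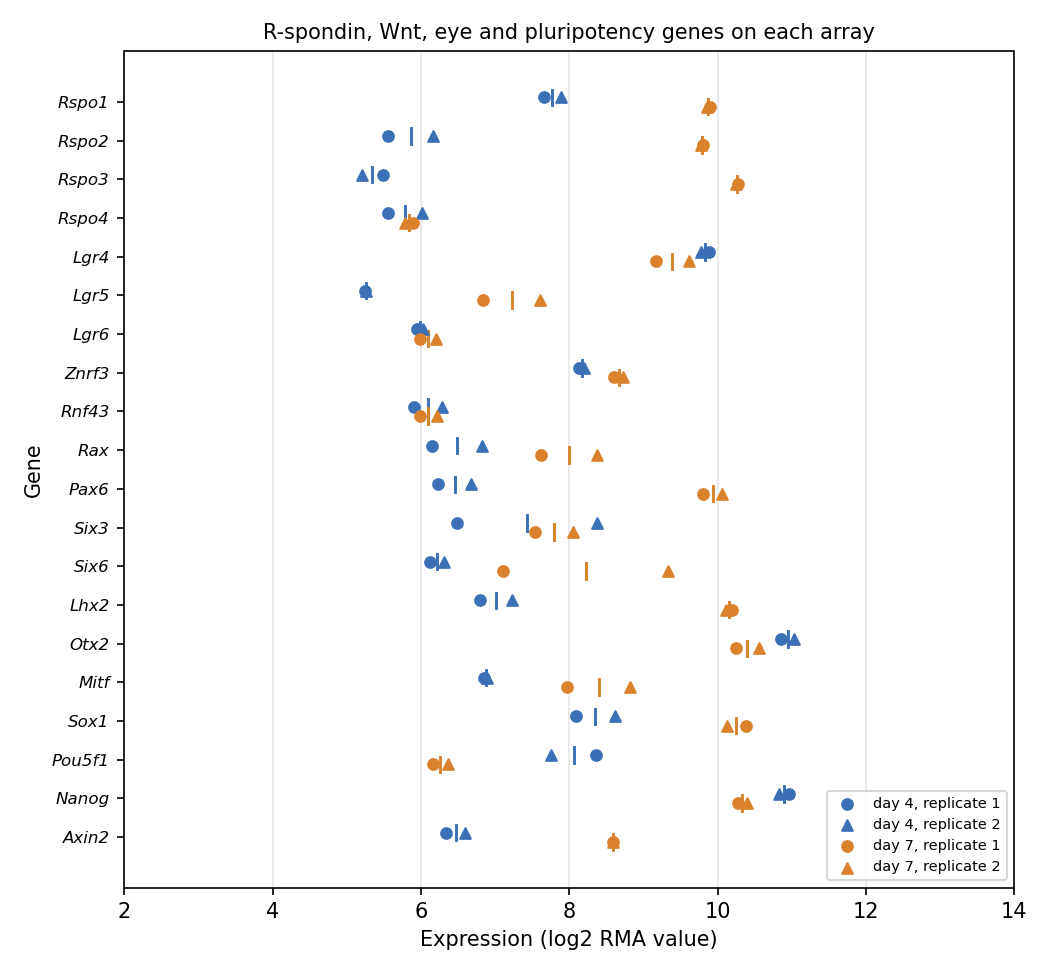
Log2 RMA signal (x axis) of R-spondin, R-spondin receptor, Wnt, eye, neural and pluripotency genes (y axis) on each of the 4 arrays, with day 4 in blue, day 7 in orange, replicate 1 as circles, replicate 2 as triangles and the mean of each day as a vertical line. The day 7 means of Rspo1, Rspo2 and Rspo3 lie between 9.79 and 10.26, that of Rspo4 is 5.84, and the day 7 points of Six6 stand far apart, at 7.11 and 9.33.

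Eye field genes split. Of 11 measured, 4 rose, 1 fell and 6 were not called (5 and 3 adjusted over the list alone). The nuclear receptor gene Nr2e1 rose 11.7-fold, Pax6 11.1-fold, from 6.46 ± 0.31 to 9.93 ± 0.17 (SD, n = 2, adjusted p = 0.000141), and Lhx2 8.86-fold. Rax rose 2.85-fold (log2 difference 1.51, SE 0.301, adjusted p = 0.021), while Hesx1 fell. Otx2 was high at both days, 10.95 ± 0.12 and 10.40 ± 0.21 (SD, n = 2, adjusted p = 0.0898, and 0.0491 with the replicate number as a block, 0.0132 to 0.463 over the alternatives). Six3 and Six6 were not called, and their replicates lay far apart. Six3 read 6.49 and 8.38 at day 4 against 7.54 and 8.06 at day 7 (log2 difference 0.36, adjusted p = 0.786, 0.0126 to 0.977 over the alternatives), and Six6 had a log2 difference of 2.00 (adjusted p = 0.0917, 0.0371 with the replicate number as a block and 0.0232 with each array centred on its median, 0.00212 to 0.29 over the alternatives). The list was shifted upwards (camera adjusted p = 0.0142, adjusted p = 0.562 with an estimated correlation), with an adjusted p of 0.209 without day 4 replicate 1 and 0.0704 on genes above the median level. Without day 4 replicate 1 the adjusted p of Rax was 0.052 and without day 7 replicate 2 it was 0.119. That of Hesx1 was 0.0748 without day 7 replicate 1 and 0.0966 without day 7 replicate 2. Six6 had a log2 difference of 3.11 without day 7 replicate 1, and Six3 one of 1.31 without day 4 replicate 2. For Six6 and Six3 the array left out was the one of its day nearest to the other day, and 1 sample then stood for its day. Taken alone, the arrays left out read otherwise. Six6 stood at 7.11 in day 7 replicate 1 against a day 4 mean of 6.22. Six3 stood at 8.38 in day 4 replicate 2, above its day 7 mean of 7.80.

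Of 20 genes of the optic vesicle and neuroretina, 9 rose and 11 were not called, with 0 lower (11 higher adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.366 with an estimated correlation). Mab21l1 rose 14.9-fold and Mab21l2 11.9-fold, both genes needed for eye formation, and Aldh1a3, a retinoic acid synthesis gene of the optic vesicle, 4.95-fold. In the list of retinal pigment epithelium genes 4 of 15 rose and 11 were not called (4 adjusted over the list alone, camera adjusted p = 0.00864, adjusted p = 0.482 with an estimated correlation). The melanin synthesis gene Dct rose 6.52-fold, Otx1 4.96-fold and Mitf, the regulator of pigment cells, 2.88-fold, from 6.87 ± 0.02 to 8.40 ± 0.60 (SD, n = 2, adjusted p = 0.0123). The fourth was the channel gene Trpm1 (log2 difference 1.49, adjusted p = 0.0088, and 0.0737 without day 7 replicate 2, 0.000916 to 0.0737 over the alternatives). In the list of retinal neurons and photoreceptors the neurogenic genes Neurod4 (3.25-fold), Isl1 (2.63-fold) and Onecut1 (1.8-fold) rose and 10 of 13 were not called (4 higher adjusted over the list alone, camera adjusted p = 0.0375, adjusted p = 0.366 with an estimated correlation). The pigment epithelium list had an adjusted p of 0.107 without day 7 replicate 2 and 0.0725 on genes above the median level. The retinal neuron list had 0.170 without day 4 replicate 1, 0.401 above the median and 0.0692 above the 25th percentile of level. Without day 7 replicate 1 or 2 the rise of Mab21l1 was 23.8-fold or 9.38-fold, that of Aldh1a3 8.79-fold or 2.79-fold and that of Dct 12.9-fold or 3.29-fold. Mab21l2 then had a log2 difference of 4.25 or 2.89 in place of 3.57. Of single genes, Aldh1a3 had 0.0756 without day 4 replicate 1 and 0.0528 without day 7 replicate 2 and Dct 0.0519 without day 4 replicate 1. Isl1 had 0.0818 without day 7 replicate 1 (0.00452 to 0.0818 over the alternatives), and Onecut1 0.126 and 0.0961 without day 7 replicate 1 or 2.

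The day 7 arrays differed from each other in these eye lists. Over the 18 genes of the eye field, optic vesicle and pigment epithelium lists with a log2 difference of at least 1, the median of replicate 2 minus replicate 1 at day 7 was 0.784. Of the 18, 15 were higher in replicate 2. Over all 46 members of these lists the median was 0.447, with 37 higher in replicate 2. Aldh1a3 read 6.60 in replicate 1 and 8.26 in replicate 2, Dct 6.69 and 8.66, and the pigment cell gene Pmel 7.62 and 10.01. Other lists differed as well. In the endoderm list 17 of 18 genes were higher in day 7 replicate 2, with a median of 0.505, and in the cholesterol synthesis list 14 of 14 were lower, with a median of -0.34. Over all genes the median was -0.014.

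Neural progenitor genes made up the group with the largest share of rises. Of 18 measured, 15 rose, 1 fell and 2 were not called (16 and 1 adjusted over the list alone, camera adjusted p = 1.39e-13, adjusted p = 0.366 with an estimated correlation). Zic1 and Pax6 were followed by the Notch effector gene Hes5 at 7.85-fold, and Sox1, an early marker of neuroectoderm, rose 3.74-fold, from 8.35 ± 0.38 to 10.25 ± 0.17 (SD, n = 2, adjusted p = 0.00185). The gene that fell was Zic5 (log2 difference -0.92, adjusted p = 0.0162, and 0.129 without day 7 replicate 1, 0.00173 to 0.129 over the alternatives). Among early neuron genes 6 of 17 rose, 2 fell and 9 were not called (10 and 3 adjusted over the list alone). Nhlh2 rose 6.05-fold, Nhlh1 3.48-fold and the doublecortin gene Dcx 3.24-fold. The neurofilament gene Ina was 3.96-fold lower at day 7 and Stmn2 1.96-fold (adjusted p = 0.0092, and 0.0946 without day 7 replicate 1, 0.000693 to 0.0946 over the alternatives). This list was shifted upwards (camera adjusted p = 0.00423, adjusted p = 0.366 with an estimated correlation, 0.252 on genes above the median level, 0.00417 to 0.252 over the alternatives).

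Forebrain genes outside the eye rose in 7 of 18 cases, with 11 not called and 0 lower (11 higher adjusted over the list alone, camera adjusted p = 4.78e-07, adjusted p = 0.366 with an estimated correlation). Wnt8b, Emx2 and Fezf2 led this list. In the list of midbrain, hindbrain and spinal cord genes 4 of 16 rose and 12 were not called (6 higher adjusted over the list alone). Wnt1, a ligand of the dorsal midline and midbrain, rose 3.2-fold to 8.25 ± 0.40 (SD, n = 2), the hindbrain gene Hoxa2 2.48-fold to 5.96 ± 0.30 (SD, n = 2), and Irx2 2.21-fold. The last of the 4 was Olig2 (log2 difference 1.06, adjusted p = 0.00766, and 0.0754 and 0.056 without day 7 replicate 1 or 2). The shift of this list (camera adjusted p = 0.000701, adjusted p = 0.43 with an estimated correlation) had an adjusted p of 0.0565 on genes above the median level (4.42e-05 to 0.0565 over the alternatives). Without day 7 replicate 2 the adjusted p of Wnt1 was 0.117 (0.00181 to 0.117 over the alternatives) and that of Irx2 0.0725 (0.00154 to 0.0725 over the alternatives).

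Genes of the primed epiblast fell in 12 of 17 cases, with 5 not called and 0 higher (13 lower adjusted over the list alone, camera adjusted p = 5.04e-13, adjusted p = 0.366 with an estimated correlation). Fgf5 and Dnmt3b fell most, and the splicing factor gene Esrp1 was 6.51-fold lower. Among general pluripotency genes 9 of 17 fell, 1 rose and 7 were not called (11 and 1 adjusted over the list alone, camera adjusted p = 1.58e-07, adjusted p = 0.366 with an estimated correlation). L1td1 was 5.93-fold lower, Utf1 5.86-fold and the Nodal co-receptor gene Tdgf1 3.65-fold. Pou5f1 (Oct4) was 3.47-fold lower, from 8.06 ± 0.43 to 6.26 ± 0.15 (SD, n = 2, adjusted p = 0.00297). The gene that rose, Lin28b (log2 difference 0.59, adjusted p = 0.0385), had an adjusted p of 0.0703, 0.0832, 0.233 and 0.195 without day 4 replicate 1, day 4 replicate 2, day 7 replicate 1 and day 7 replicate 2. The naive pluripotency list was not called (camera adjusted p = 0.222, 0.0379 without day 7 replicate 2, 0.0379 to 0.951 over the alternatives, adjusted p = 0.716 with an estimated correlation), with 2 of 17 genes lower and 15 not called (3 lower adjusted over the list alone). Nanog belonged to the uncalled ones, at 10.90 ± 0.10 and 10.33 ± 0.09 (SD, n = 2, adjusted p = 0.0531, and 0.0461 with quantile normalization, 0.00457 to 0.309 over the alternatives). The fall of Nr0b1 (log2 difference -1.18, adjusted p = 0.015) had 0.0757 and 0.111 without day 7 replicate 1 or 2, and that of Gdf3 (-1.03, 0.0226) had 0.161 and 0.0959.

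Signalling lists mostly moved up. In the BMP and TGF-beta list 6 of 21 genes rose, 1 fell and 14 were not called (10 and 1 adjusted over the list alone, camera adjusted p = 0.000163, adjusted p = 0.366 with an estimated correlation). The ligand gene Bmp5 (8.79-fold), Id4, a BMP target gene (7.34-fold), and Bmp7 (4.9-fold) led, and Gdf3 fell by 1.03 log2 (adjusted p = 0.0226, and 0.161 and 0.0959 without day 7 replicate 1 or 2). Notch pathway genes rose in 10 of 18 cases with 0 lower and 8 not called (12 higher adjusted over the list alone, camera adjusted p = 5.55e-08, adjusted p = 0.366 with an estimated correlation). Hes5 was followed by Nrarp at 4.78-fold and the ligand gene Jag1 at 4.13-fold. Hedgehog pathway genes rose in 5 of 12 cases with 0 lower and 7 not called (8 higher adjusted over the list alone, camera adjusted p = 3.65e-05, adjusted p = 0.366 with an estimated correlation). Those not called included the ligand gene Shh, dim at both days (means of 4.43 and 4.24, adjusted p = 0.685). They also included the receptor gene Ptch1 (log2 difference 0.08, adjusted p = 0.866) and Hhip (-0.24, adjusted p = 0.519). The shift of this list therefore does not show a rise in pathway activity. The co-receptor genes Boc (6.33-fold) and Gas1 (3.93-fold) and the transcription factor gene Gli3 (3.53-fold) rose most. Cdon came next (log2 difference 1.32, adjusted p = 0.0145, and 0.0822 without day 7 replicate 2, 0.00184 to 0.0822 over the alternatives), then Gli1 (0.63, adjusted p = 0.0471). Gli1 had 0.1, 0.0822, 0.108 and 0.302 without day 4 replicate 1, day 4 replicate 2, day 7 replicate 1 and day 7 replicate 2. For retinoic acid, 7 of 16 genes rose, 1 fell and 8 were not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.377 with an estimated correlation, 0.0565 on genes above the median level, 2.44e-06 to 0.0565 over the alternatives). The retinoic acid binding protein gene Crabp1 rose 6.39-fold and the retinol transporter gene Stra6 3.88-fold (5.93-fold and 2.54-fold without day 7 replicate 1 or 2). The receptor gene Rarg was 2.19-fold lower (adjusted p = 0.00587, and 0.0604 without day 7 replicate 2, 0.00173 to 0.0604 over the alternatives). The FGF and ERK list went the other way, with 6 of 19 genes lower, 1 higher and 12 not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.00459, adjusted p = 0.377 with an estimated correlation). Besides Fgf5, the feedback inhibitor gene Spry4 was 3.29-fold lower and the transcription factor gene Etv5 2.41-fold (adjusted p = 0.00529, and 0.0578 without day 7 replicate 1, 0.000327 to 0.0578 over the alternatives). The receptor gene Fgfr3 was 2.27-fold higher (adjusted p = 0.0147, and 0.0781 without day 7 replicate 1, 0.00396 to 0.0781 over the alternatives).

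Genes of epithelial junctions and polarity fell in 10 of 17 cases, 2 rose and 5 were not called (11 and 2 adjusted over the list alone, camera adjusted p = 5.63e-06, adjusted p = 0.366 with an estimated correlation). E-cadherin (Cdh1) was 4.69-fold lower, from 11.46 ± 0.07 to 9.23 ± 0.29 (SD, n = 2, adjusted p = 0.000575), and Epcam 4.41-fold. N-cadherin (Cdh2) was 5.78-fold higher, from 9.35 ± 0.28 to 11.88 ± 0.03 (SD, n = 2, adjusted p = 0.000325), and the polarity gene Crb2 5.2-fold. The basement membrane list was not called (camera adjusted p = 0.125, 0.00514 without day 7 replicate 1, 0.00514 to 0.738 over the alternatives, adjusted p = 0.686 with an estimated correlation), with 2 of 16 genes higher, 1 lower and 13 not called (4 and 1 adjusted over the list alone). The nidogen gene Nid1 (log2 difference 1.00, adjusted p = 0.0355) and the collagen gene Col4a2 (0.90, 0.0359) were higher and the laminin gene Lama5 (-0.90, 0.0253) lower. Without day 7 replicate 2 these 3 had adjusted p-values of 0.158, 0.214 and 0.0554 (Nid1 then differed by 0.65). Without day 4 replicate 2 they had 0.0689, 0.0882 and 0.0639. Nid1 had 0.0676 without day 4 replicate 1 and Lama5 0.185 without day 7 replicate 1.

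Genes of glycolysis and the hypoxia response fell in 5 of 16 cases, with 11 not called and 0 higher (10 lower adjusted over the list alone, camera adjusted p = 3.13e-05, adjusted p = 0.366 with an estimated correlation). The peptide hormone gene Adm was 4.01-fold lower, Egln3, an oxygen-sensing hydroxylase gene, 3.52-fold, and Bnip3 2.24-fold. Pfkp and Ldha, genes of glycolytic enzymes, had log2 differences of -1.14 (adjusted p = 0.00413, and 0.0513 without day 7 replicate 1, 0.000115 to 0.0513 over the alternatives) and -1.02 (0.0293, and 0.192 and 0.108 without day 7 replicate 1 or 2). Bnip3 had an adjusted p of 0.0255, which was 0.0637 without day 4 replicate 1 and 0.11 without day 7 replicate 1. In the DNA methylation and Polycomb list 6 of 17 genes fell and 11 were not called (8 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.0259, adjusted p = 0.366 with an estimated correlation). Dnmt3b, Phc1 (2.94-fold lower) and Cbx7 (2.66-fold lower) came first. That list had 0.066 without day 4 replicate 1 and 0.0524 on genes above the median level.

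No gene (0) of 19 in the cell cycle list was called by limma, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.263, adjusted p = 0.767 with an estimated correlation). The mitotic checkpoint gene Bub1 had the largest difference (-0.47, adjusted p = 0.0924, and 0.0471 on genes above the median level, 0.00891 to 0.386 over the alternatives). The same held for cholesterol synthesis, with 0 of 14 genes called, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.868, adjusted p = 0.962 with an estimated correlation). Nsdhl differed most there (0.28, adjusted p = 0.411). In the p53 and unfolded protein list Cdkn1a (p21) was 2.09-fold higher, Ddit4 and Trib3 were 1.91-fold and 1.87-fold lower. In this list 14 of 17 genes were not called (1 and 2 adjusted over the list alone, camera adjusted p = 0.105, 0.0483 without day 7 replicate 1, 0.0483 to 0.243 over the alternatives, adjusted p = 0.377 with an estimated correlation). Cdkn1a had 0.0659 without day 7 replicate 1 (0.000176 to 0.0659 over the alternatives). Ddit4 had 0.0601, 0.18 and 0.0565 and Trib3 0.0811, 0.0623 and 0.209 without day 4 replicate 2, day 7 replicate 1 and day 7 replicate 2. Of 10 housekeeping genes 0 were called by limma, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.531, adjusted p = 0.687 with an estimated correlation). The largest difference was that of Gusb (-0.39, adjusted p = 0.142).

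Imprinted genes, expressed from 1 parental copy, rose in 7 of 17 cases, with 2 lower and 8 not called (9 and 4 adjusted over the list alone, camera adjusted p = 0.00309, adjusted p = 0.366 with an estimated correlation). Plagl1 led, Ndn rose 3.0-fold and Peg12 2.98-fold (adjusted p = 0.0089, and 0.0725 without day 7 replicate 1, 0.00126 to 0.0725 over the alternatives). The growth factor adaptor gene Grb10 was 6.75-fold lower, and the non-coding RNA Meg3 1.98-fold (adjusted p = 0.00572, and 0.0522 and 0.0616 without day 7 replicate 1 or 2). Among germline genes 3 of 15 fell and 12 were not called (4 lower adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.366 with an estimated correlation). The piRNA pathway genes Mael and Ddx4 were 3.95-fold and 3.37-fold lower and Slc25a31 1.55-fold. The germline list had 0.0926 without day 4 replicate 1, 0.153 without day 7 replicate 1 and 0.154 on genes above the median level. Ddx4 had 0.0513 and 0.0565 without day 7 replicate 1 or 2. Slc25a31 (adjusted p = 0.0467) had 0.134, 0.145 and 0.289 without day 4 replicate 1, day 7 replicate 1 and day 7 replicate 2, 0.0678 with quantile normalization and 0.0561 with each array centred on its median.

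Markers of other cell types moved too. Neural crest genes rose in 8 of 14 cases, with 1 lower and 5 not called (12 and 2 adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.366 with an estimated correlation). Of the 14, 5 also stood in another list. Tfap2b rose 9.73-fold, Pax3 5.83-fold and Sox9, also a neural progenitor gene, 4.88-fold (2.94-fold and 8.09-fold without day 4 replicate 1 or 2). Foxd3, also an epiblast gene, was 2.07-fold lower. Fibroblast and mesenchyme genes rose in 6 of 14 cases, with 1 lower and 7 not called (9 and 1 adjusted over the list alone, camera adjusted p = 8.17e-05, adjusted p = 0.366 with an estimated correlation). The smooth muscle actin gene Acta2 rose 10.4-fold to 10.05 ± 0.07 (SD, n = 2), Prrx1 6.24-fold and Postn 2.99-fold. The surface protein gene Thy1 was 5.26-fold lower. Trophoblast genes rose in 4 of 12 cases (Tfap2c 5.32-fold, Tpbpa 3.39-fold, Rhox6 2.47-fold and Cited1 by 0.97 log2). Eomes was 2.19-fold lower and 7 were not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.377 with an estimated correlation). The trophoblast list had 0.0603 without day 7 replicate 2 and 0.0672 on genes above the median level. Without day 4 replicate 1, day 7 replicate 1 and day 7 replicate 2, Foxd3 had 0.0638, 0.0666 and 0.171. Without day 7 replicate 1 or 2, Sox9 had 0.0903 and 0.0838 and Cited1 0.0567 and 0.0678. Rhox6 had 0.0791, 0.0875 and 0.11 (a log2 difference of 0.76 in place of 1.30) without day 4 replicate 1, day 4 replicate 2 and day 7 replicate 2.

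Lists of the remaining cell types were not called. In surface ectoderm and lens, Tfap2c and the lens gene Prox1 (1.89-fold, adjusted p = 0.00783, and 0.0857 without day 7 replicate 1, 0.00309 to 0.0857 over the alternatives) rose. The other 14 of 16 genes were not called (4 higher adjusted over the list alone, camera adjusted p = 0.0521, adjusted p = 0.564 with an estimated correlation). The list passed at 0.00724 without day 4 replicate 2 and 0.00514 without day 7 replicate 1. In primitive streak and mesoderm, Kdr (1.92-fold) rose, Eomes fell and 13 of 15 genes were not called (2 and 1 adjusted over the list alone, camera adjusted p = 0.59, adjusted p = 0.877 with an estimated correlation). In endothelium and blood the VEGF receptor genes Flt1 (2.35-fold, adjusted p = 0.0132) and Kdr rose and 12 of 14 were not called (2 adjusted over the list alone, camera adjusted p = 0.301 upwards, adjusted p = 0.65 with an estimated correlation). Its median difference was -0.04 and its mean 0.22. In definitive and extraembryonic endoderm Cxcr4 (5.64-fold), Pdgfra (3.21-fold) and Sox17 (1.71-fold) rose and 15 of 18 were not called (3 adjusted over the list alone, camera adjusted p = 0.868 upwards, adjusted p = 0.962 with an estimated correlation). The median difference was -0.08 and the mean 0.09. Cxcr4 and Pdgfra are also expressed outside endoderm. The endoderm list passed upwards without day 7 replicate 1 (adjusted p = 0.0336) and downwards without day 7 replicate 2 (adjusted p = 0.0422). Kdr (adjusted p = 0.0259) had 0.0553, 0.0505 and 0.148 without day 4 replicate 1, day 4 replicate 2 and day 7 replicate 2. Flt1 had 0.0672 without day 7 replicate 2 (0.00187 to 0.0672 over the alternatives), and Sox17 (adjusted p = 0.0321) 0.092, 0.139 and 0.205 without day 4 replicate 1, day 7 replicate 1 and day 7 replicate 2.

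**Figure D3:**
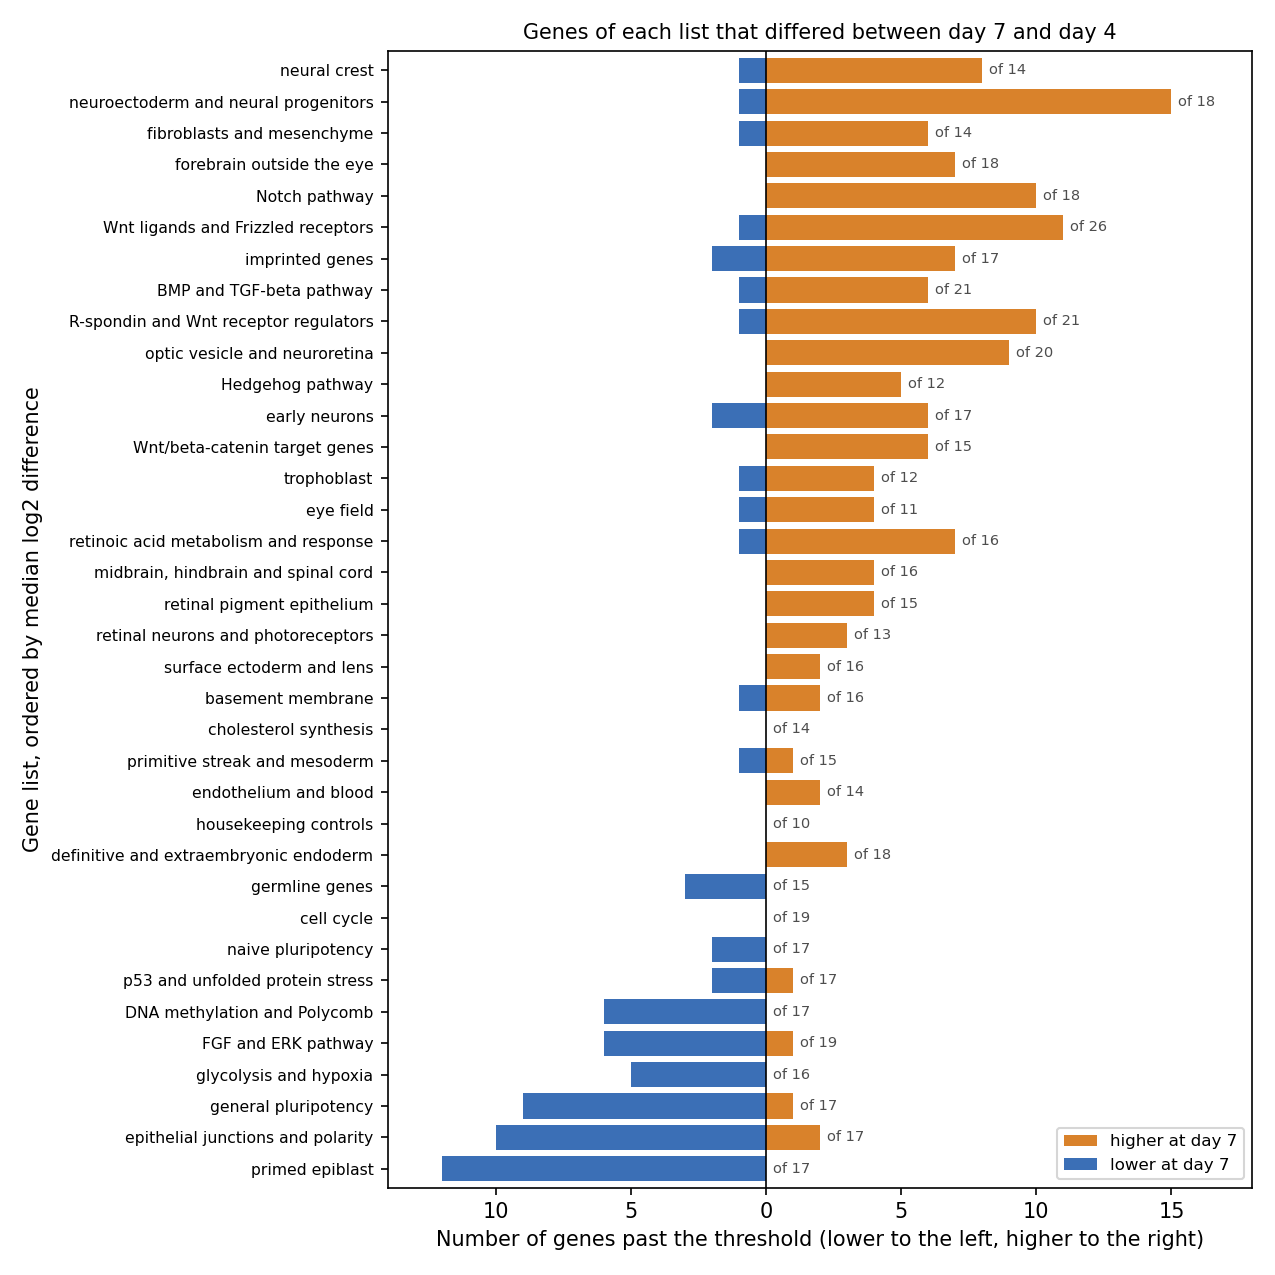
Number of genes (x axis) of each of the 36 fixed lists (y axis, ordered by median log2 difference) that were higher at day 7 (orange, to the right) or lower (blue, to the left) at an adjusted p under 0.05, with the number of measured genes beside each bar. Neuroectoderm has the most genes higher, 15 of 18, and primed epiblast the most lower, 12 of 17.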

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

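All alternatives in this part were chosen before the data were examined. The number of genes that differed between the days was 2324, and leaving out 1 array gave 887 to 2500. It moved to 1078 at an adjusted p under 0.01, to 1323 of 41345 when all probe sets were tested and to 3 without a variance prior, where 0 genes were at least 2-fold different and 930 of that size had an unadjusted p under 0.05. A fit without a prior has 2 residual degrees of freedom. Quantile normalization (2484), centring on the median (2709), both level filters (2521 and 2705), a trend in the prior (2975, and 3058 with robust estimation), the mean of a gene's probe sets (2340) and an adjusted p under 0.1 (3343) stayed within 1.5 times. The number at least 2-fold different, 1160, was 887 to 1387 without 1 array and otherwise, except without a prior, 944 to 1211. No scaling moved the median difference of all genes by more than 0.1 log2.

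The replicate number entered as a replicate block gave 2770 genes, 2307 of them shared with the 2324, and the same 26 lists. With it Six6 (adjusted p = 0.0371, 0.00212 to 0.29 over the alternatives) and Otx2 (0.0491, 0.0132 to 0.463) passed. Arrays of the same number deviated from their group means with r = 0.186 across genes, which are not independent replicates, but no label ties the numbers to a shared batch and there are 2 pairs, so the numbers were not treated as a pairing.

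The 26 called lists were 22 to 29 without 1 array, 17 of the 35 testable ones on genes above the median level, where fewer genes were tested, 0 with an estimated correlation (adjusted p from 0.366 to 0.562 for the 26), and 3 with fry, where 13 of the 26 had an adjusted p under 0.06. With the preset correlation 17 of the 26 were called under each alternative. The endoderm list, not called with all arrays, reversed to lower without day 7 replicate 2 (adjusted p = 0.0422) and was called higher without day 7 replicate 1, with 0.0336 to 0.886 over the 4 arrays left out, and the cause was not tested. Of 131 named genes 119 were called, 83 of them under each alternative apart from the fit without a variance prior, the set of all probe sets and the other adjusted p limits, which were run for the counts alone, and 36 lost the call without at least 1 array. Hesx1 and Slc25a31 (2 genes) lost it with another scaling or variance prior, while Nanog, Otx2, Six6, Znrf3 and Bub1, not called with the main settings, passed under at least 1 alternative that kept all arrays. Signs changed 6 times, in 4 uncalled genes. On genes above the median level 118 named genes kept their status and 3 gained a call. The other named genes fell below that filter, so the 83 include dim genes that were not tested there. Signal over background limits dim genes, for which no background measure was used here.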

Other observations

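Of the tests in this part, those of day 4 replicate 2 were set before their results were seen, and the others, as well as the genes named here, were chosen after. Among genes outside the lists, the axon guidance gene Slit2 rose 15.0-fold, from 6.40 ± 0.05 to 10.31 ± 0.19 (SD, n = 2), its receptor gene Robo2 11.9-fold, and the netrin receptor genes Dcc and Unc5c 8.38-fold and 7.2-fold. The homeobox genes Meis1 and Meis2, expressed in eye and forebrain, rose 11.4-fold and 6.88-fold, the nuclear receptor gene Nr2f1 10.7-fold, and the POU genes Pou3f3 and Pou3f2 11.3-fold and 3.74-fold. Lmx1a rose 4.07-fold, Gdf7 3.47-fold and Olig3 5.83-fold (8.96-fold and 3.79-fold without day 7 replicate 1 or 2). These genes were picked singly, and no list holding them was tested.

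Mir9-2, a neural microRNA gene left out by the naming rule, was at least 34.1-fold higher at day 7, from 2.97 ± 0.07 to 8.06 ± 0.41 (SD, n = 2, limma adjusted p = 5.97e-05), a lower bound with respect to background alone, because its day 4 mean lay under the 25th percentile of all genes (4.60). All 5 measured genes of the Mir302 cluster of pluripotent cells were called lower, with log2 differences from -5.93 to -2.95. Hprt was low on every array, at 4.50 ± 0.04 and 4.63 ± 0.45 (SD, n = 2), at percentile 24.4 of all genes.

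Genes between Meg3 and Dio3 on chromosome 12, an imprinted region with many microRNA genes, were mostly lower at day 7. Of 52 measured, limma called 33 lower and 0 higher, and the median difference was -1.3. Dio3os (0.28) and a predicted gene beside Dio3 were not lower. In 47 of the 52 both day 7 values lay below both day 4 values, against 16.7% by chance. Over all genes the days did not overlap in 50.8%, counting both directions, against 33.3% by chance. The 52 genes are neighbours and not independent. The day 4 arrays stood apart in these genes too, with replicate 2 below replicate 1 in 48 of 52 and a median of replicate 2 minus replicate 1 of -0.715, so the median difference was -1.74 against replicate 1 alone and -0.93 against replicate 2 alone. A general loss of signal from small RNA probe sets is argued against by the 95 microRNA genes elsewhere above the median level, with a median of -0.0162 (bootstrap 95% interval -0.0875 to 0.0705, 5 lower and 3 higher), and loss of a copy of chromosome 12 by 405 other genes of that chromosome above the median level, with a median of 0.0415 (0.00693 to 0.0794). Genes, which are not independent replicates, were the units of both intervals. Whether these probe sets read mature microRNAs or longer transcripts was not tested. A candidate explanation is lower transcription of the region's non-coding genes with differentiation, which these values cannot decide. Rian (log2 difference -0.58, adjusted p = 0.113) and Meg3 (-0.99, adjusted p = 0.00572) were lower in both day 7 arrays. Both belong to the 52 genes, so their fall is part of the pattern and no separate support for a cause. The protein-coding flanks Dlk1 (1.19, SE 0.59, adjusted p = 0.294, and a difference of 0.17 without day 7 replicate 2) and Dio3 (0.24, adjusted p = 0.584) were not called. That does not show that the flanks stayed level. Rian itself did not pass the test, and a change in the imprint or in the mix of cells stays open.

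The genes of the 3 eye lists differed between the day 7 arrays, by a median of 0.447 log2 over all 46 members, 37 of which were higher in replicate 2, and by 0.784 over the 18 with a day difference of at least 1. A difference in scale common to all genes is argued against by all 18 forebrain genes, which lay at -0.11 with 5 of 18 higher, a difference of medians of 0.557 (permutation test, two-sided, p = 0.0001). A difference in quality that acts unevenly on genes stays open, since this comparison cannot detect it. Fewer forebrain cells with more of every other type in their place stays open: the 14 neural crest genes lay at 0.07 with 8 of 14 higher, a difference of 0.377 (permutation test, two-sided, p = 0.0185) that did not reach the limit of 0.5 set for the test, and the endoderm list was higher in 17 of 18 genes. Genes, which are not independent replicates, were the units in both tests, which compare these 2 arrays and not conditions. A larger share of eye tissue in replicate 2 may account for the difference in eye genes and was not tested. By itself it would not account for the endoderm list, whose median difference was 0.505.

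Day 4 replicate 2 lay nearer to day 7 than replicate 1 did, with a median displacement of 0.151 log2 over the 1160 genes that differed at least 2-fold, 66.7% of which were nearer. A narrower range of values on that array is argued against as the whole cause, because 71.2% of the displacement (bootstrap 95% interval 56.3 to 83.9) was left after subtracting that of uncalled genes at the same day 4 level. A later stage of those aggregates may account for the rest, since what was left had the direction of day 7 both in rising genes (0.0495, interval 0.022 to 0.0885) and in falling ones (0.187, interval 0.157 to 0.245). Genes, which are not independent replicates, were the units of these intervals, which compare the day 4 arrays and not cultures. Hesx1 went the other way, at 7.75 in replicate 1 and 10.12 in replicate 2 before its fall by day 7, and differences in RNA quality or in noise between the day 4 arrays stay open.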
